A study of Mus musculus with 6 samples.

How the data were processed

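Cortex RNA of 3 FAD5x and 3 C57BL/6 Control samples was sequenced, 1 library per sample. Per the labels' protocols, total RNA was extracted from flash frozen cortex with TRIzol and a column kit, and the library preparation is not given in the sources used here, nor is its strandedness. Per the submitters' processing notes, the tools were cutadapt, STAR 2.7.11b, featureCounts, edgeR 3.38.4 and limma, with the mouse genome build GRCm39, and the notes give no order or parameters. The authors deposited raw counts per gene, 47729 lines keyed by Ensembl gene identifier, with a column for each library. One line had a cell that was not a number and was left out, which left 47728 genes. Whether reads that map to several places were counted is not given in the sources used here. Near-identical genes such as mt-Co3 and its nuclear copy Gm28437 had almost equal counts, so counts of genes with close copies are uncertain.

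Libraries were matched to samples by the library names in the labels, and groups were taken from the treatment label. Total counts were 17363946 to 24137936 per library, and the tested genes held 99.8% of them. Gene symbols and types came from a GENCODE annotation of an earlier mouse build, matched by identifier, with 47223 identifiers matched and 505 not, and no coordinates are given because the builds differ. Neighbouring genes were ordered by that annotation.

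Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test with a robust prior, after filtering on the 2 groups with the filterByExpr function and scaling by the trimmed mean of M values. The design held an intercept and the genotype, tests were two-sided, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The biological coefficient of variation was 23.3%, and the median log2 fold change of all tested genes was 0.02. CPM values were computed from the deposited counts.

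A total of 51 gene lists were fixed before the data were examined, for ribosome, mitochondria, glia, immune, synapse, signalling and stress genes and for markers of other cell types, neighbouring brain regions and sex. Of their entries 34 were matched through a synonym and 3 were not measured. The 49 lists with at least 3 tested members were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over these lists. Lists share members, such as Ctsz and C1qa, and so are not independent. With an estimated correlation no list was called, although 3 had an unadjusted p below 0.05. The rule for named genes, also fixed before, took the transgene loci, among them App and Thy1, then the 10 risen and 10 fallen called genes with the smallest p whose groups do not overlap, leaving out predicted genes without a symbol of their own, then up to 4 called members per described list, or, with none called, the 2 with the highest mean level. Some genes that the rule takes are not reported here. Genes named outside that rule are said to have been chosen after their values were seen. Of the called genes, 91 had no symbol of their own.

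The steps were tested on simulated counts for 17074 genes with the means, spread and library sizes of these data. With no gene changed, 0 genes and 0 lists were called. The genes were drawn independently of each other. The 0 lists therefore do not show how camera with its preset correlation behaves where genes vary together. Of 100 genes changed 2-fold 77% were called, and of 100 changed 4-fold 99%, with 16 calls among unchanged genes. The changed genes were drawn only from genes with a mean level above the median, so these shares do not cover genes with low counts. A 1.5-fold shift of the ribosomal protein genes led both of their lists and 1 other list to be called, with 0% of the genes called singly.

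Alternatives covered the test (limma-voom, DESeq2 1.42.0), the scaling, the filter on low counts, a replicate block, a sex covariate, gene classes left out, thresholds and each library left out in turn. After the data were seen, 4 more were added: processed pseudogenes left out, length and GC trends taken out, and 2 pairs of libraries left out. Copies of ribosomal protein genes were sought by aligning their transcripts to other transcripts, at an identity of 95% over 50% of the length.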

Results

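RNA sequencing measured transcript levels in the cerebral cortex of FAD5x mice, a model of Alzheimer's disease that carries human transgenes with familial disease mutations, and of C57BL/6 mice as Control. Each group held 3 libraries, and the deposited table gave counts for 47728 genes in all 6 libraries. Total counts were 24137936, 22626806 and 17972967 in FAD5x replicates 1, 2 and 3, and 17363946, 18188112 and 18056893 in Control replicates 1, 2 and 3. The title of the series names the ribosome and signalling pathways of this tissue as its subject. The single comparison of the design asked which transcripts differ between the groups. The labels do not state whether the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. FAD5x replicates 1 and 2 have related library names. Their counts differed with a chi-square of 64.8 per degree of freedom, against 42.4 and 61.1 for the other FAD5x pairs, and they were counted as separate samples. Control replicate 1 had 3 Xist counts and 3124 counts in Y-linked genes, whereas the other 5 libraries had 10346 to 22631 Xist counts and at most 9 Y-linked counts. In what follows, fold changes are FAD5x over Control on the log2 scale with their standard error (SE), and levels are in CPM, counts relative to the library total, scaled by the normalisation factors unless stated.

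Thy1 (ENSMUSG00000032011), a neuronal surface glycoprotein gene whose promoter cassette drives the transgenes of this model, rose 3.08-fold in FAD5x cortex (log2 1.62 ± 0.34 SE, n = 3 per group; edgeR quasi-likelihood test, adjusted p = 0.0456). Its level was 1476, 702 and 1749.7 CPM in FAD5x replicates 1, 2 and 3, and 345, 398 and 532 CPM in Control replicates 1, 2 and 3. App (ENSMUSG00000022892), the amyloid precursor protein gene, had a log2 fold change of 0.27 ± 0.22 that did not pass the test (adjusted p = 0.528), with 1387, 1743 and 1059.7 CPM in FAD5x and 1052, 1076 and 1354 CPM in Control. Reads from the human transgenes can align in part to the mouse genes, so these values do not measure the transgenes themselves. The Thy1 call ended without FAD5x replicate 1 (adjusted p = 0.104), FAD5x replicate 3 (0.0598), Control replicate 1 (0.185), Control replicate 2 (0.164) or Control replicate 3 (0.0937). It also ended with library totals only, with a sex covariate, which marked only Control replicate 1, with protein-coding genes only, and with length and GC trends taken out.

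In FAD5x cortex 300 genes rose and 237 fell among 17074 tested. The protein-coding genes that rose with the smallest p included Hapln2, a link protein of the nodes of Ranvier (7.19-fold, log2 2.85 ± 0.25, adjusted p = 0.00129), and Nkx6-2, an oligodendrocyte transcription factor (3.75-fold, log2 1.91 ± 0.18, adjusted p = 0.00143). Adi1, an enzyme of methionine salvage, rose 3.12-fold (adjusted p = 0.000843), Alad, an enzyme of haem synthesis, 3.58-fold (0.00178), and Ass1, an enzyme of arginine synthesis, 3.06-fold (0.00472). Cd14, a lipopolysaccharide co-receptor of myeloid cells, rose from 2.36 ± 0.09 to 9.06 ± 1.23 CPM (SD, n = 3), or 3.84-fold (adjusted p = 0.00456). Nudc, a dynein-associated protein, rose 2.09-fold, Cfap54, a cilium component, 3.93-fold and Plekhb1 2.92-fold (adjusted p = 0.00262, 0.00474 and 0.00533). Eno1b, an enolase gene nearly identical to Eno1, rose 5.48-fold (log2 2.45 ± 0.13, adjusted p = 6.03e-05), and its count is uncertain because reads can be shared with Eno1. Eno1, singled out after its values were seen, was not called (log2 fold change -0.19 ± 0.14, adjusted p = 0.494), and the sum of both genes was 93.7%, 90.1% and 107% of the Control mean in FAD5x replicates 1, 2 and 3, against 97.2% to 101% in Control. All 537 called genes had FAD5x and Control libraries that did not overlap, as did 4673 of all tested genes, against 10% by chance. Of the called genes 321 changed by a log2 of at least 1, 181 of them higher and 140 lower, and 29 of the risen genes were processed pseudogenes, against 4 of the fallen. The count of called genes was 204 without FAD5x replicate 1, 989 without FAD5x replicate 2, and 98, 81 and 152 without Control replicates 1, 2 and 3. Of the 10 risen genes named here only Plekhb1 lost its call when single libraries were left out (adjusted p = 0.0567 without Control replicate 2). DESeq2 called 1485 genes, a fit with no filter on low counts 1063 and a fit with sex as a covariate 94, and leaving out FAD5x replicate 1 and Control replicate 1 together, a choice made after the data were seen, called 34. The sex covariate marked only Control replicate 1, so its fit is close to leaving that library out and does not separate sex from that library.

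Among fallen genes with a symbol of their own, Rpl29 (ENSMUSG00000048758), a protein gene of the large ribosomal subunit, had the smallest p and was 35.4-fold lower in FAD5x (log2 fold change -5.15 ± 0.24, adjusted p = 4.42e-05). Rpl29 stood at 3.17, 5.18 and 4.23 CPM in FAD5x replicates 1, 2 and 3 and at 128, 183 and 134 CPM in Control replicates 1, 2 and 3. Among zinc finger genes, Zfp965 was 15.0-fold lower, Zfp969 12.3-fold, Zfp966 10.1-fold, Zfp968 8.16-fold and Zfp967 7.10-fold (adjusted p = 0.00132, 0.00178, 0.00373, 0.000843 and 0.00123). Col3a1, a fibrillar collagen, was 10.4-fold lower (adjusted p = 0.00178) and Eln, elastin, 5.39-fold lower (adjusted p = 0.00413). Nrep, a gene of growing and regenerating neurons, was 3.68-fold lower (adjusted p = 0.00215) and Fam177a 2.29-fold lower (adjusted p = 0.00187). All 10 of these calls held when each library was left out in turn. Rpl29 has processed copies and the zinc finger genes belong to a multigene family, so reads can be split between copies and these counts are uncertain. Gm8210, a processed copy of Rpl29, had 143, 149 and 189 CPM in FAD5x and 1.15, 1.21 and 0.609 CPM in Control, over deposited totals. Gm13841, another copy, had 166, 167 and 215 CPM in FAD5x and 1.27, 1.54 and 0.775 CPM in Control, and both were singled out after their values were seen.

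**Figure D1:**
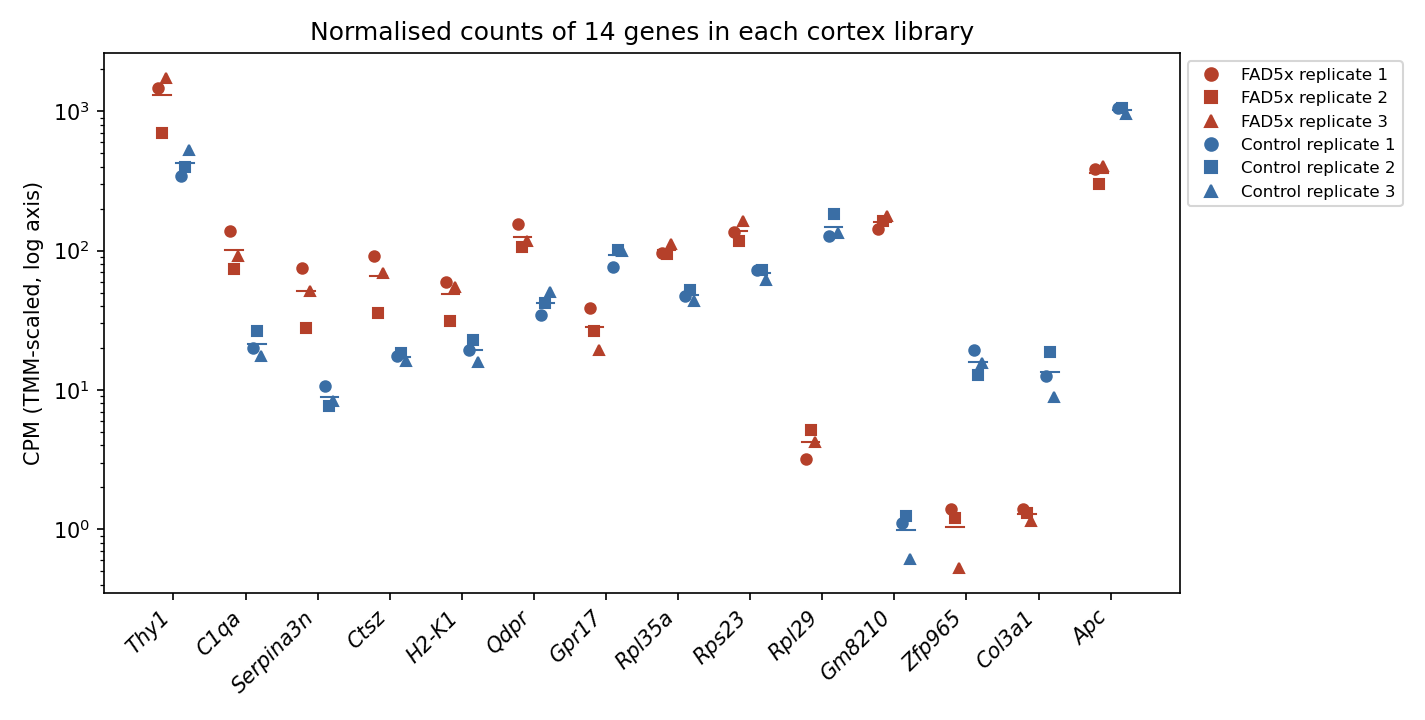
Levels of selected called genes in each library, in CPM on a log axis, with the replicates as symbols, FAD5x and Control in separate colours, and bars at the group means. Rpl29 lies between 3.17 and 5.18 CPM in the FAD5x libraries and between 128 and 183 CPM in the Control libraries.

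Genes for cytosolic ribosomal proteins, the structural proteins of the translating ribosome, were higher in FAD5x as a class. Of 49 large-subunit genes 22 rose and 1, Rpl29, fell, and adjusted over the list alone 46 rose and 1 fell. Of 34 small-subunit genes 13 rose and 0 fell (edgeR, with 0 lower at an unadjusted p under 0.05, by limma-voom and by DESeq2), and adjusted over the list alone 29 rose. Rpl35a rose 2.11-fold (log2 1.08 ± 0.13, adjusted p = 0.00575), Rpl37 1.96-fold (adjusted p = 0.0158) and Rpl11 1.71-fold (0.0176). Rps23 rose 2.01-fold (log2 1.01 ± 0.15, adjusted p = 0.0160), Fau 1.83-fold (0.0220), Rps15 1.88-fold (0.0235) and Rps10 1.81-fold (0.0236). The median log2 fold change was 0.64 over the large subunit and 0.66 over the small subunit, with 48 of 49 and 33 of 34 genes above 0. In single libraries the large-subunit median, relative to the Control mean, was 0.61, 0.57 and 0.80 in FAD5x replicates 1, 2 and 3 and -0.05, 0.15 and -0.11 in Control replicates 1, 2 and 3. The camera test of limma, with its preset correlation, called both lists (adjusted p = 4.33e-26 and 2.17e-18), and with an estimated correlation neither was called (adjusted p = 0.596 and 0.622). The number of large-subunit genes called higher was 3, 32 and 14 without FAD5x replicates 1, 2 and 3 and 1, 2 and 1 without Control replicates 1, 2 and 3, and that of small-subunit genes was 1, 22 and 7 and 0, 1 and 0. With length and GC trends taken out, a choice made after the data were seen, 12 and 7 genes were called higher. The direction of both medians was the same under each scaling tried, and 70 of 83 genes have a near-identical copy, so that single counts are uncertain.

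**Figure D2:**
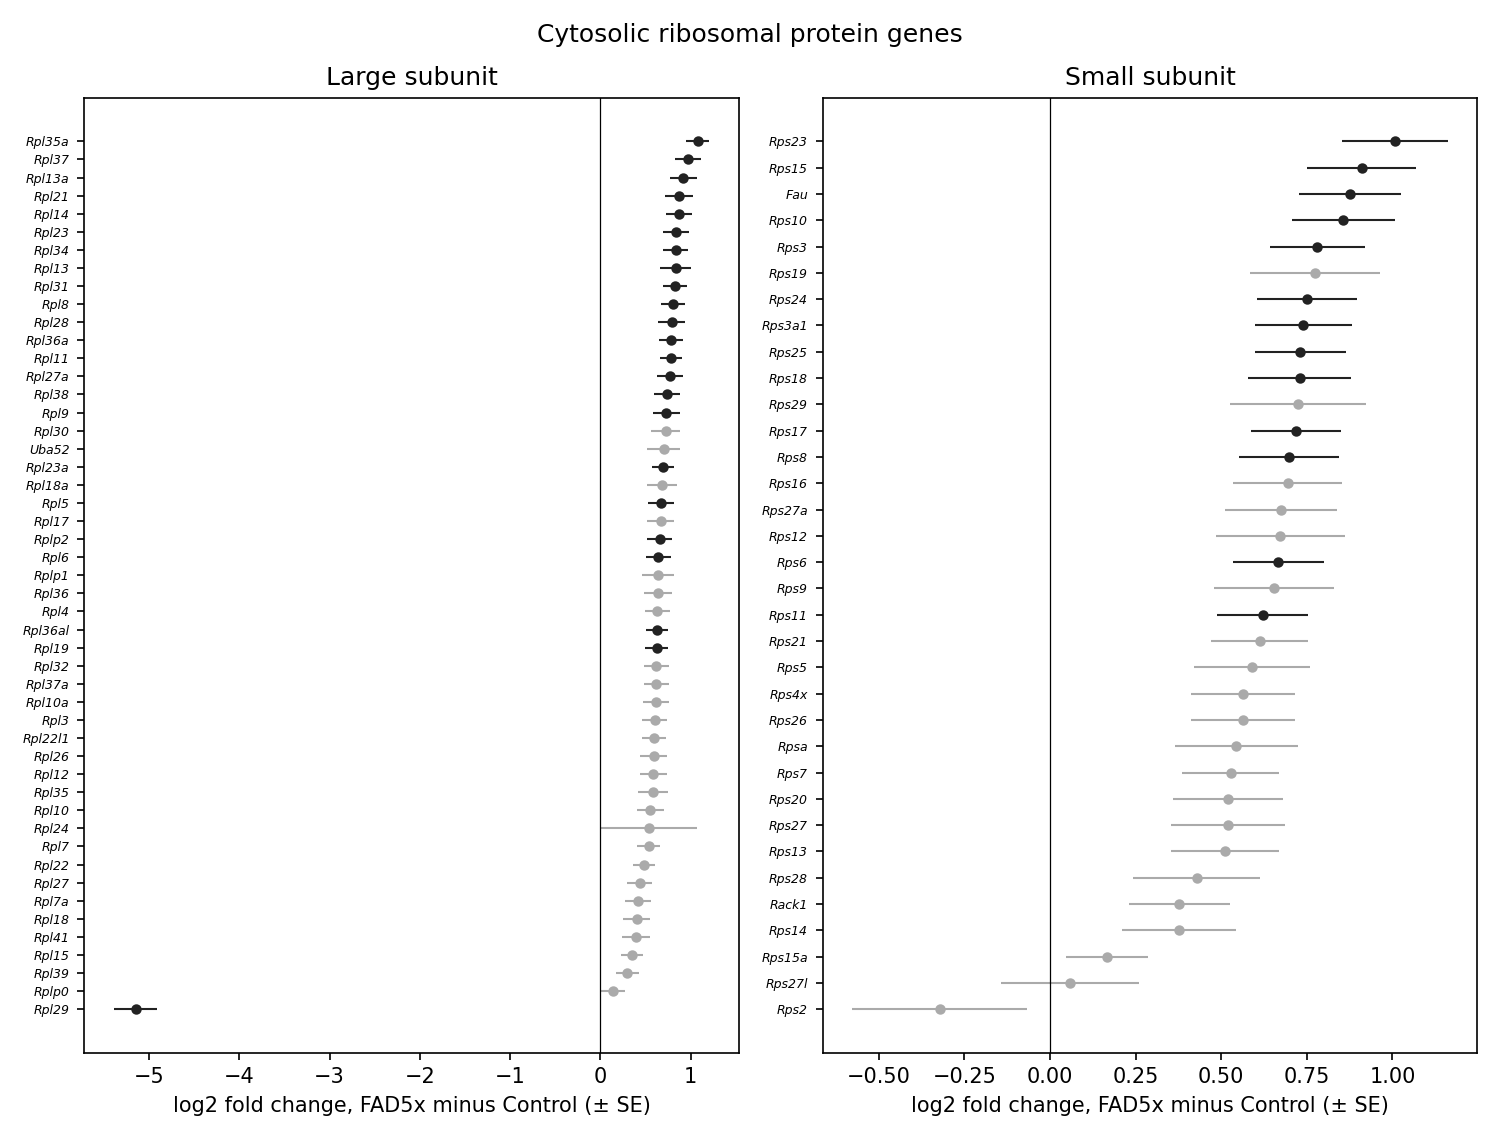
Log2 fold change, FAD5x over Control, of each cytosolic ribosomal protein gene of the large and small subunit, with bars of 1 standard error, called genes in black and others in grey. Except for Rpl29, at -5.15, and 1 small-subunit gene, the genes lie above 0, and the medians are 0.64 and 0.66.

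Other parts of the translation and respiration machinery had smaller shifts in the same direction. They were near the median of 0.17 (quartiles -0.01 and 0.35) of 504 other genes with length and level like the cytosolic ribosomal protein genes. The translation factor and ribosome biogenesis medians, both 0.12, lay below it. Those 504 genes were chosen after the data were seen and were not matched to the lists below. Whether these shifts exceed a trend with length and level was therefore not tested. Of 77 mitochondrial ribosomal protein genes 2 rose, Mrps18a 1.52-fold (log2 0.60 ± 0.12, adjusted p = 0.0392) and Mrpl23 1.62-fold (0.70 ± 0.15, 0.0449), and the list median was 0.25. Of 75 nuclear genes for oxidative phosphorylation subunits 3 rose, Ndufb8 1.60-fold (adjusted p = 0.0211), Cox5b 1.5-fold (0.0458) and Ndufa13 1.47-fold (0.0476), with 73 of 75 above 0, a median of 0.25 and 6 risen when adjusted over the list alone. Among 41 translation factors Eif3g (1.61-fold, adjusted p = 0.0286) and Eif3k (1.47-fold, 0.0356), both subunits of an initiation factor, and Eef1g (1.54-fold, 0.0483), an elongation factor subunit, rose, and 7 rose when adjusted over the list alone. Of 40 ribosome biogenesis genes Nhp2, a component of small nucleolar ribonucleoproteins, rose 1.56-fold (adjusted p = 0.0494), and 0 did when adjusted over the list alone (edgeR, with 5 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom). Of 13 mitochondrially encoded transcripts mt-Atp8 rose 1.95-fold (log2 0.96 ± 0.14, adjusted p = 0.0143), but that list was not called (camera adjusted p = 0.310). Mitochondrial counts are shared with nuclear copies, and the copy Gm28437 had 99.7% to 99.9% of the count of mt-Co3. Camera called the lists of mitochondrial ribosomal proteins (adjusted p = 5.51e-07), oxidative phosphorylation (2.99e-11), translation factors (0.00189) and ribosome biogenesis (0.0374). With an estimated correlation none of these was called (adjusted p = 0.650, 0.650, 0.650 and 0.622 in that order). The translation factor list lost its call without FAD5x replicate 2 (adjusted p = 0.0794) and the ribosome biogenesis list without FAD5x replicate 2 or Control replicate 2 (0.139 and 0.0986). Over 23 settings with the preset correlation, 21 called the translation factor list and 17 the ribosome biogenesis list. The number of genes called in each of these 4 lists was 0 without any one Control library, and mt-Atp8 lost its call without Control replicate 1 or 3.

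Genes known to be induced around amyloid plaques were higher in FAD5x cortex, with 10 of 53 risen and 0 fallen over all genes (edgeR, with 1 lower at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom). Adjusted over the list alone, 34 rose and 1 fell. C1qa, a chain of the complement initiator C1q, rose 4.72-fold (log2 2.24 ± 0.26, adjusted p = 0.00726), and Serpina3n, a serine protease inhibitor of reactive astrocytes, 5.77-fold (2.53 ± 0.35, 0.0146). Ctsz, a lysosomal protease, rose 3.79-fold (1.92 ± 0.31, 0.0231) and S100a6, a calcium-binding protein, 2.31-fold (1.21 ± 0.22, 0.0275). Of 25 genes of disease-associated microglia 3 rose, Ctsz, Fth1, the ferritin heavy chain (2.09-fold, adjusted p = 0.0328), and Lgals3, a galectin of activated phagocytes (7.21-fold, 0.0387). Of these 25 genes 15 rose and 1 fell when adjusted over the list alone. Of 17 complement genes C1qa and Itgb2, the beta subunit of complement receptors (3.18-fold, adjusted p = 0.0340), rose, and 6 rose when adjusted over the list alone. Of 20 homeostatic microglia genes Slc2a5, a fructose transporter, fell 3.19-fold (adjusted p = 0.0369), and 6 rose and 3 fell when adjusted over the list alone. This list had a median of 0.44, with 14 genes above 0, and was not called (camera adjusted p = 0.219). The medians of the plaque-induced, microglial and complement lists were 0.92, 1.09 and 1.17, and camera called all 3 (adjusted p = 3.63e-16, 3.96e-07 and 0.000291). With an estimated correlation none was called (adjusted p = 0.626, 0.650 and 0.596). FAD5x replicate 2 stood apart from the other FAD5x libraries here: its plaque-induced median, relative to the Control mean, was 0.26, against 1.35 and 0.92 in FAD5x replicates 1 and 3, and 0.25 in Control replicate 2. Without FAD5x replicate 2, 39 of 55 plaque-induced genes and 21 of 29 microglial genes rose, and without FAD5x replicates 1 and 3 the counts were 3 and 9, and 1 and 2. Without any one Control library they were 1 and 0. The number of complement genes risen was 1, 6 and 4 without FAD5x replicates 1, 2 and 3 and 1 without any one Control library, and Slc2a5 kept its call only without FAD5x replicate 2. The homeostatic list was called higher without FAD5x replicate 2 or Control replicate 2 (adjusted p = 0.00505 and 0.0258).

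Antigen presentation genes of MHC class I rose in FAD5x, with 6 of 15 called over all genes and 13 when adjusted over the list alone. H2-K1, a classical class I heavy chain, rose 2.52-fold (log2 1.33 ± 0.26, adjusted p = 0.0358), and the non-classical genes H2-T23 and H2-T22 rose 2.25-fold (0.0314) and 2.05-fold (0.0236). H2-Q6 had a log2 fold change of 4.08 ± 0.61 (adjusted p = 0.0147), from a mean of 0.129 CPM in Control. Of 7 MHC class II genes H2-DMb1, a peptide-loading chaperone subunit, rose 8.62-fold (adjusted p = 0.0171). Of 34 lysosomal genes Ctsz and Ctss, a protease of antigen-presenting cells (3.50-fold, adjusted p = 0.0369), rose, and 11 rose when adjusted over the list alone. Ifi27 (2.24-fold, adjusted p = 0.0289) was the single called gene of 26 interferon response genes, whose list was not called (camera adjusted p = 0.148, with 0.00273 without FAD5x replicate 2 and 0.0283 without Control replicate 2). Camera called class I (median 1.18, adjusted p = 1.48e-09), class II (2.52, 0.0469) and the lysosome (0.31, 5.12e-06), and with an estimated correlation none was called (adjusted p = 0.596, 0.650 and 0.622). The class II median, relative to the Control mean, was 3.0 and 3.18 in FAD5x replicates 1 and 3 and -0.46 in FAD5x replicate 2. The class II list lost its call without FAD5x replicate 1 or 3 or Control replicate 3 (adjusted p = 0.116, 0.116 and 0.159). H2-DMb1 lost its call without FAD5x replicate 1 (0.0559) or any one Control library (0.0732, 0.0966 and 0.0711). Ifi27 kept its call only without FAD5x replicate 2, and the number of lysosomal genes risen was 1, 12 and 2 without FAD5x replicates 1, 2 and 3 and 0 without any one Control library. The number of class I genes risen was 0, 10 and 3 without FAD5x replicates 1, 2 and 3 and 1, 0 and 0 without Control replicates 1, 2 and 3. Class I genes are a polymorphic family with shared sequence, so their counts are uncertain where strains differ.

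Among glia, myelin and oligodendrocyte genes were higher in FAD5x, with 6 of 20 risen over all genes and 8 when adjusted over the list alone. Qdpr, a pteridine reductase (2.99-fold, log2 1.58 ± 0.19, adjusted p = 0.00615), Ermn, a cytoskeletal protein of myelinating cells (2.97-fold, 0.0207), Gpr37, an oligodendrocyte receptor (3.22-fold, 0.0211), and Myrf, the regulator of myelin genes (2.79-fold, 0.0324), rose. Of 15 markers of oligodendrocyte precursors and their differentiating progeny, Bcas1, a gene of early myelinating cells, rose 3.25-fold (adjusted p = 0.0104), and Gpr17, a receptor of differentiating precursors, fell 3.28-fold (0.0147). The precursor list was not called (camera adjusted p = 0.0501). Of 28 reactive astrocyte genes 5 rose, among them Serpina3n, Cd14, Aspg (3.73-fold, adjusted p = 0.0222) and Srgn, a proteoglycan of secretory granules (2.02-fold, 0.0358). General astrocyte markers had 0 called genes among 20 (edgeR, with 1 at an unadjusted p under 0.05 and 0 by limma-voom and DESeq2) and a camera adjusted p of 0.648. Log2 fold changes were -0.32 ± 0.29 for the glutamate transporter gene Slc1a2 and 0.61 ± 0.25 for Clu. Camera called the myelin list (median 0.60, adjusted p = 2.50e-06) and the reactive astrocyte list (median 0.27, 0.0456), and neither with an estimated correlation (adjusted p = 0.650 for both). The myelin median, relative to the Control mean, was 1.13, 0.18 and 0.46 in FAD5x replicates 1, 2 and 3 and 0.33 in Control replicate 3. FAD5x replicate 1 also had 49.2 CPM of the striatal receptor gene Drd2 over deposited totals, against 1.21 to 1.88 CPM in the other libraries, a gene singled out after its values were seen. The reactive astrocyte list lost its call without FAD5x replicate 1 or 3 or Control replicate 3 (adjusted p = 0.0801, 0.135 and 0.312), and the precursor list was called lower without FAD5x replicate 1 or Control replicate 1 (0.00058 and 0.0119). The number of reactive astrocyte genes risen was 2, 8 and 3 without FAD5x replicates 1, 2 and 3 and 1 without any one Control library. Bcas1 lost its call without Control replicate 1 or 2 and Gpr17 without Control replicate 2 or 3, and the number of myelin genes risen was 3, 8 and 6 without FAD5x replicates 1, 2 and 3 and 1, 0 and 4 without Control replicates 1, 2 and 3.

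Synaptic genes of the excitatory postsynaptic side were lower in FAD5x, with 2 of 30 fallen over all genes and 6 when adjusted over the list alone. Homer2, a scaffold of metabotropic glutamate receptors, was 1.96-fold lower (log2 fold change -0.97 ± 0.19, adjusted p = 0.0365). Presynaptic vesicle genes had 0 called members among 26, and GABA receptor genes 0 among 15, by edgeR, limma-voom and DESeq2. At an unadjusted p under 0.05 edgeR had 2 higher and 2 lower presynaptic genes, and 1 higher and 2 lower GABA receptor genes. Snap25, a vesicle fusion protein gene, had a log2 fold change of 0.75 ± 0.30 and the GABA receptor gene Gabbr1 of 0.15 ± 0.17. Of 20 excitatory neuron markers Etv1, a transcription factor of layer 5 neurons, fell 1.79-fold (adjusted p = 0.0373), a call that held in single-library omissions only without FAD5x replicate 2. Camera called the glutamate receptor and postsynaptic density list (median -0.26, adjusted p = 7.60e-06) and not with an estimated correlation (adjusted p = 0.596). It did not call the presynaptic, GABA receptor and excitatory neuron lists (0.417, 0.236 and 0.208). The presynaptic list had a median of -0.11 and a mean of 0.02. Without FAD5x replicate 2 the presynaptic, GABA receptor and excitatory neuron lists were called lower (adjusted p = 0.00273, 0.0229 and 0.0011), and the excitatory list also without Control replicate 1 (0.0434). The number of called postsynaptic genes was 5 and 2 without FAD5x replicates 2 and 3, 0 without FAD5x replicate 1, Control replicate 1 or Control replicate 2 and 1 without Control replicate 3.

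In the Wnt, cAMP, PI3K-Akt-mTOR and MAPK signalling lists 4 genes were called, all lower, in the Wnt list and the calcium and cAMP list. Apc, a scaffold of the complex that degrades beta-catenin, was 2.82-fold lower in FAD5x (log2 fold change -1.49 ± 0.17, adjusted p = 0.00438), at 363 ± 55 CPM against 1024 ± 64 CPM in Control (SD, n = 3). The Wnt receptor gene Fzd1 was 2.0-fold lower (adjusted p = 0.0369) and the ligand gene Wnt4 1.98-fold lower (0.0460), so that 3 of 30 Wnt genes fell, and 2 rose and 5 fell when adjusted over the list alone. Pde4d, a cAMP phosphodiesterase, was 2.05-fold lower (adjusted p = 0.0313) among 37 calcium and cAMP genes. By edgeR 0 of 30 PI3K-Akt-mTOR genes and 0 of 30 MAPK genes were called, with 1 higher and 4 lower, and 3 higher and 3 lower, at an unadjusted p under 0.05. DESeq2 called 1 higher and 1 lower, and 2 higher, and limma-voom called 0. Among their most abundant members, the kinase gene Gsk3b had a log2 fold change of -0.31 ± 0.14 and the neurotrophin receptor gene Ntrk2 of 0.00 ± 0.16. Camera called the PI3K-Akt-mTOR list lower (median -0.16, adjusted p = 0.0389), and not with an estimated correlation (adjusted p = 0.650). It did not call the Wnt, calcium and cAMP, and MAPK lists (0.0900, 0.0687 and 0.283). The PI3K-Akt-mTOR list lost its call without FAD5x replicate 3 or Control replicate 3 (adjusted p = 0.237 and 0.0541) and with length and GC trends taken out (0.333, a choice made after the data were seen). In all it was called in 18 of 23 settings with the preset correlation. Apc kept its call without any one library, Fzd1 and Pde4d only without FAD5x replicate 2, and Wnt4 only without FAD5x replicate 2 or Control replicate 1. The Wnt list was called lower without Control replicate 3 (0.0131), and the calcium and cAMP list without FAD5x replicate 2, Control replicate 1 or Control replicate 2 (0.00113, 0.0324 and 0.0283).

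Vascular and meningeal genes were lower in FAD5x. Of 23 endothelial and mural markers Kdr, a receptor for vascular endothelial growth factor, was 2.15-fold lower (log2 fold change -1.10 ± 0.20, adjusted p = 0.0282) and Itm2a 1.77-fold lower (-0.83 ± 0.18, 0.0487), and 6 fell when adjusted over the list alone. All 15 meningeal and fibroblast markers had a negative fold change, Col3a1 passed the test, and 2 fell when adjusted over the list alone. Camera called the endothelial list (median -0.40, adjusted p = 0.000378) and the meningeal list (median -1.25, 2.50e-06), and neither with an estimated correlation (adjusted p = 0.622 for both). The meningeal median, relative to the Control mean, was -1.05, -2.89 and -0.48 in FAD5x replicates 1, 2 and 3 and 0.19, 0.46 and -0.63 in Control replicates 1, 2 and 3, so that Control replicate 3 lay below FAD5x replicate 3. The number of endothelial genes fallen was 1, 3 and 0 without FAD5x replicates 1, 2 and 3 and 0 without any one Control library, and that of meningeal genes was 6 without FAD5x replicate 3.

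**Figure D3:**
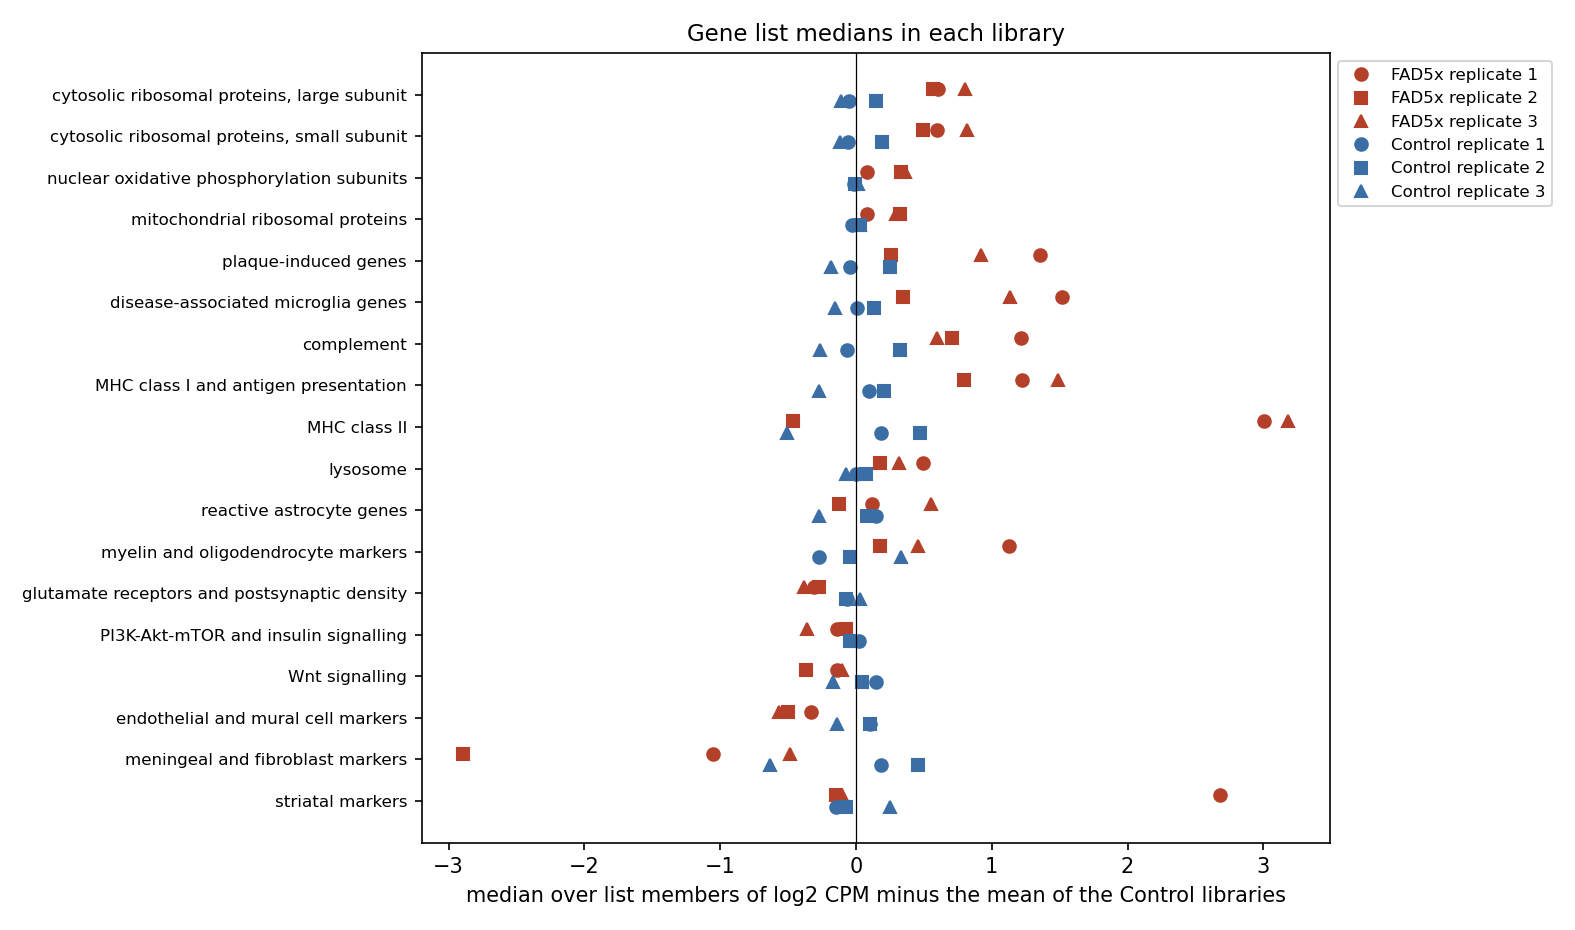
Median over the members of each gene list of log2 CPM minus the mean of the Control libraries, 1 point per library, with FAD5x and Control in separate colours. The large-subunit ribosomal protein medians lie at 0.57 to 0.80 in the FAD5x libraries, whereas the plaque-induced medians lie at 1.35, 0.26 and 0.92 in FAD5x replicates 1, 2 and 3.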

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

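Settings added after the results were seen were processed pseudogenes left out, length and GC trends taken out, and 2 pairs of libraries left out, and the other 22 of 26 were planned. The count of called genes, 537, was 1485 with DESeq2 with or without independent filtering, which left 12 adjusted p-values undefined in both, 1063 with no filter beyond 1 count, 94 with a sex covariate, 897 without FAD5x replicates 1 and 2 and 34 without FAD5x replicate 1 and Control replicate 1. It was 321 at a log2 fold change of at least 1, 1251 at an adjusted p under 0.1 and 3635 at an unadjusted p under 0.05, and 81 to 989 with 1 library left out. The sex covariate marked only Control replicate 1, so its fit is close to leaving that library out, which called 98. Other settings gave 417 to 555 genes, or 715 with FAD5x replicates 1 and 2 summed. The replicate block called 72 genes by title number and 41 by library name. Samples with the same title number had correlated deviations of -0.04, -0.09 and -0.31, which gave no sign of pairing by that number. By the number in the library name, FAD5x replicates 1 and 2 had -0.04 and -0.21 with Control replicate 1, and FAD5x replicate 3 had 0.04 with Control replicate 2. So few libraries cannot exclude pairing by either number. Control replicate 3 shares its library-name number with no other library, so it adds nothing to the comparison in that block.

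Of the transgene loci Thy1 was called, and 0 loci were called with library totals only, protein-coding genes only, length and GC trends taken out, a sex covariate, either replicate block, and FAD5x replicate 1 and Control replicate 1 left out, and 0 to 1 with 1 library left out. The cause was not tested.

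Of 49 lists 24 were called, and 20 to 30 in the other fits, 0 with an estimated correlation and 0 by the directional fry test, where 13 had an unadjusted p under 0.05, while the mixed fry test called 30 and ranks 25. The ribosomal protein lists kept medians of 0.64 and 0.66 with adjusted p of 0.596 and 0.622 by estimated correlation and 0.0941 for both by fry, and the plaque-induced list 0.92 with 0.626 and 0.188. Both ribosomal protein, mitochondrial ribosomal protein, oxidative phosphorylation, plaque-induced, microglial, complement, class I, lysosome, myelin, endothelial, meningeal and postsynaptic lists were called in all 23 settings with the preset correlation that could change a list call. None of them was called with an estimated correlation or by the directional fry test. The other 3, limma-voom, no robust prior and DESeq2 without independent filtering, repeated the list p-values of another fit and say nothing about the lists. Among 77 named called genes limma-voom kept 59, totals only 60, length and GC trends taken out 52, a sex covariate 26, the blocks 21 and 10, and leaving out FAD5x replicates 1, 2 and 3 or Control replicates 1, 2 and 3 kept 37, 75, 54, 27, 25 and 30. Without the 3 settings that repeated list p-values, 69 list results gained a call over all lists and settings, 108 lost one and 1095 kept their side. No called value changed sign, and sign changes between values called in neither fit were not counted. The median of all genes lay within 0.04 of 0 under each scaling. With 3 libraries per group, changes near 2-fold were missed in part in the simulated counts, which changed only genes above the median level.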

Other observations

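The tests of a swapped label, depth and transgene carriage for FAD5x replicate 2, of length and GC trends, of the summed Rpl29 copies and of neighbouring genes were chosen only after the results were seen, as were the gene lists for cortical maturation. Genes named in the paragraphs on single libraries were also chosen after their values were seen.

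Among further lists of cell functions, the proteasome, circadian, cytokine and glycolysis lists were called, none of them with an estimated correlation. Of 31 proteasome genes Psmc5, a base subunit, rose 1.54-fold (log2 0.62 ± 0.13, n = 3 per group; edgeR adjusted p = 0.0458), and camera called the list (median 0.14, adjusted p = 0.00182; 0.124 with length and GC trends taken out and 0.650 with an estimated correlation). Of 17 heat shock genes Cryab, a small chaperone, rose 2.03-fold (adjusted p = 0.0373), and its list was not called (0.304). Bhlhe41, a clock repressor, rose 2.02-fold (adjusted p = 0.0314) in a circadian list called at 0.0439 (0.650 with an estimated correlation) that lost its call without FAD5x replicate 1, FAD5x replicate 2 or Control replicate 2 (0.137, 0.0993 and 0.0986). Ch25h, which makes 25-hydroxycholesterol, rose 8.94-fold (adjusted p = 0.0314), in a cholesterol list that was not called (0.208, but 0.0411 without FAD5x replicate 2). Spi1, a myeloid transcription factor, rose 2.38-fold (adjusted p = 0.0376) among 26 mouse counterparts of Alzheimer risk genes, whose list was not called (0.0546) but passed without FAD5x replicate 2, FAD5x replicate 3 or Control replicate 2 (0.0252, 0.0440 and 0.0283). Cxcl12, a chemokine of vessels and meninges, fell 2.06-fold (adjusted p = 0.0458) in a cytokine list called higher (0.0439; 0.650 with an estimated correlation). That list lost its call without FAD5x replicate 1 or Control replicate 3 (0.228 and 0.0742) and was called in 14 of the 23 settings with the preset correlation that could change a list call. Psmc5 and Spi1 kept their calls only without FAD5x replicate 2 (0.0413 and 0.0190), with adjusted p of 0.0571 to 0.201 and 0.0514 to 0.154 in the other omissions. Bhlhe41, Ch25h and Cxcl12 lost theirs without any one Control library (0.101 to 0.115, 0.0505 to 0.139 and 0.0979 to 0.159). Cryab lost its call without Control replicates 1 and 2 in turn (0.126 and 0.147). Without FAD5x replicate 1, Cryab and Bhlhe41 were not called (0.0948 and 0.0753), nor was Cxcl12 without FAD5x replicate 3 (0.0717). The 19 glycolysis genes had 0 called members (edgeR, with 3 higher and 1 lower at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom). Aldoa had a log2 fold change of 0.43 ± 0.17, and the list was called higher at 0.0389 but not without FAD5x replicate 2 (0.418) or Control replicate 1 (0.0683), nor with an estimated correlation (0.650). The glycolysis and circadian lists were each called in 15 of the 23 settings with the preset correlation.

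Among further lists for cells and regions, the inhibitory neuron list and the thalamic and hypothalamic list were called. Reln, a secreted protein of cortical interneurons, fell 2.36-fold (log2 fold change -1.24 ± 0.24, adjusted p = 0.0365), and its inhibitory neuron list was called lower (median -0.27, adjusted p = 0.0307; 0.596 with an estimated correlation), though not without FAD5x replicate 1 (0.104). Reln lost its call without FAD5x replicate 1 (0.0999) or any one Control library (0.134, 0.105 and 0.0829). Thalamic and hypothalamic markers were called lower as a list (median -0.70, adjusted p = 0.00946; 0.596 with an estimated correlation), with 0 of 14 genes called by edgeR, 1 higher and 3 lower at an unadjusted p under 0.05, 2 lower by DESeq2 and 0 by limma-voom. Striatal markers were not called (0.0501), though 12 of 23 settings with the preset correlation called them. Among single-library omissions these were the fits without FAD5x replicate 2, FAD5x replicate 3 or Control replicate 3 (0.00215, 0.00153 and 0.0411). The striatal median, relative to the Control mean, was 2.68 in FAD5x replicate 1 and -0.15 and -0.10 in FAD5x replicates 2 and 3. The choroid plexus list had a median of 0.01 and a mean of -0.36, the red blood cell list a median of -0.20 and an upward test, and the stress response list a median of -0.12 and a mean of 0.01, and none was called (0.288, 0.743 and 0.304). With single libraries left out, the red blood cell list was called without Control replicate 3 (0.00110), with 0 of its genes called higher and 1 lower in that fit. The red blood cell median of Control replicate 3, relative to the Control mean, was -1.78. The stress response list was called without FAD5x replicate 2 (0.0247). The immediate early and histone lists had medians of 0.09 and 0.06 and a downward test. Immediate early, hippocampal, histone, autophagy, amyloid processing and blood leukocyte lists were not called (0.896, 0.902, 0.933, 0.960, 0.310 and 0.273).

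FAD5x replicate 2 lay near the Control libraries for plaque-associated genes: the microglial gene Cst7 had 1165, 16 and 602 counts in FAD5x replicates 1, 2 and 3 and 7, 7 and 2 in Control, and the astrocyte gene Gfap had 1516, 117 and 973 CPM over deposited totals against 202, 165 and 118. Without that library Cst7 had an edgeR adjusted p of 4.88e-05 and Gfap of 0.0012, against 0.104 and 0.168 with it. Both genes were chosen after these values were seen, so the smaller p-values are no separate evidence. Some values went the other way. C1qa had 73.3 CPM in FAD5x replicate 2 against 17.5 to 26.7 CPM in Control. The complement and class I medians of FAD5x replicate 2, relative to the Control mean, were 0.71 and 0.80, against at most 0.33 and 0.21 in a Control library. A wrongly labelled Control sample is argued against. Of 989 genes called between the other FAD5x libraries and Control, 63.5% lay nearer FAD5x in replicate 2. The share was 86.8% and 65.5% for FAD5x replicates 1 and 3, and at most 9.21% for any left-out Control library. Each share rests on the genes called without the library in question. Low depth is also argued against, since the total of FAD5x replicate 2 was 107% of the mean of the other FAD5x libraries. A littermate without the transgenes stays open: Thy1 was at 702 CPM in it, above the Control libraries and below the other FAD5x libraries. The labels give no age or sex and do not state whether the libraries came from separate animals, so a biological difference of that sample may also account for it and was not tested.

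Ribosomal protein transcripts were higher in FAD5x in all 3 libraries. A transcript length or GC trend is argued against as the whole cause, since the median over 83 genes was 0.49 with those trends taken out, from 0.64, and 504 other genes of like length and level had a median of 0.17. Reads shared with pseudogene copies are argued against, since the 13 genes without a close copy had a median of 0.69, all above 0, against 0.64 for the 70 with one. A difference in RNA handling between the groups, or a change in cell types or in ribosome production in FAD5x cortex, may each account for the rest and was not tested. The large-subunit median of FAD5x replicate 2, 0.57, was close to that of replicate 1 although its plaque-associated genes were not.

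Rpl29 and the 5 named zinc finger genes lay far apart between the groups, with no overlap between their libraries. The summed counts of Rpl29 and its copies did not lie below the Control range in FAD5x, but this cannot settle the level of Rpl29. With the processed copy Gm8210, singled out after its values were seen, the sum was 97.8%, 103% and 130% of the Control mean in FAD5x replicates 1, 2 and 3. It was 88.8% to 121% in Control. With all 27 near-identical copies it was 227%, 234% and 302% in FAD5x. The size of the sum depends on the copies taken, and a read can be counted in several of them. Whether reads counted in the copies came from Rpl29 was not tested, so lower transcription of Rpl29 itself stays open. Strain variants in chromosome blocks stay open: called genes formed 37 neighbouring pairs of different families, above the highest of 10000 permutations, 31 (p = 1e-04, the smallest they can give), but the 537 genes with the smallest p in another split of the libraries, none of them called, also formed 37. That split keeps part of any group difference, so its pairs do not measure chance. Families were set by the stem of the gene symbol, with all predicted genes without a symbol of their own taken as a single family. Pairs with the same stem, such as neighbouring Zfp genes, were left out of these counts. A Zfp gene beside a predicted gene of the same cluster still counted as a pair of different families. On chromosome 2, 41 called genes fell and 20 rose among 1357 tested, the most fallen genes of any chromosome by count. By share it did not stand alone, since on chromosome 18 13 fell and 6 rose among 446 tested. Younger Control animals may account for part of the other calls and cannot be told apart from the genotype because the labels give no age: genes that fall with cortical maturation had a median of -0.69, with 19 of 25 negative, and were called lower (camera adjusted p = 3.79e-05; 0.598 with an estimated correlation). Genes that rise with it had a median of 0.23 and were not called (0.135), except without FAD5x replicate 3 or Control replicate 3 (0.00162 and 0.00526), and their median was -0.04 without FAD5x replicate 2.

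The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split called 537 genes and 1 of the 10 gave as many, itself, and the highest other split called 0 by edgeR, with 178 to 1217 genes at an unadjusted p under 0.05 in the others against 3635. Every other split mixed FAD5x and Control libraries on both sides, so a group difference would widen the spread within its sides. The 0 calls there therefore cannot serve as a measure of chance. For gene lists 3 of the 10 splits gave at least the 24 of the real split, and the highest other gave 28. Each of the ribosomal protein lists was called by camera in 7 of the 9 other splits, with medians of at most 0.35 and 0.41 in size, against 0.64 and 0.66 in the real split. All 24 lists were also called in at least 1 other split, 17 of them with as small an adjusted p, and 6 had a median as large in size in another split. These were the meningeal, myelin (0.74 against 0.60), class II (2.81 against 2.52), reactive astrocyte (0.50 against 0.27), proteasome (0.21 against 0.14) and circadian (0.23 against 0.19) lists. The other splits hold unequal shares of FAD5x libraries on their sides, so part of a group difference stays in them. Their list calls therefore cannot show how often lists are called with no difference.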
